A study of Mus musculus with 33 samples.

How the data were processed

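Libraries were made from total RNA of mP4 mouse pancreatic organoids, extracted from Matrigel domes with a column kit and a DNase step and prepared for DNBSEQ sequencing, per the labels' protocols. Reads were checked with FastQC 0.11.5 and MultiQC, trimmed with Trim Galore 0.4.4 and quantified with Salmon 1.3.0 for the genome build GRCm38.p6 (mm10), per the submitters' processing notes. The deposited estimated counts are Salmon's, rounded to whole numbers in the files, and the deposited TPM values are transcripts-per-million from the same step. The annotation release, the strand setting and the way transcripts were summed to genes are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart, and near-identical family members can exchange reads, so genes that share 10% or more of their exonic length with another gene are named as uncertain.

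The files hold 54347 gene identifiers in each of 33 libraries, of which 54094 matched a symbol and a location in the GENCODE M21 annotation of GRCm38. The others held at most 0.006% of the counts of a library. Between 3 and 27 genes per library had a count of 0 and a TPM above 0, as rounding gives. Totals of 38000470 to 39875124 counts leave depth nearly equal between groups. Levels in the text are counts-per-million scaled by TMM factors, with their SD over n libraries.

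Groups came from the labels: 12 controls of week 1, 3 controls of week 12, and 3 libraries each adapted to, or acutely treated with, erlotinib, gemcitabine or both. The labels give no replicate numbers that groups share, so replicate numbers here follow accession order and were not used to pair libraries. No library was left out. Deviations from group means were later used to find the culture sets, by the assignment with the highest mean correlation among 216. The sets found this way follow the accession order in all 12 libraries, a hint that same-numbered libraries belong together, though the labels do not say so. The fits with a term for these sets were added after the data were seen. Their counts can be too high, since the sets were found from the same values.

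Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filter for low counts of edgeR and robust dispersion estimates, and called at a Benjamini-Hochberg adjusted p under 0.05. All 21 week-12 libraries shared a fit with a mean per group (15888 genes), and the 15 controls shared another for week 12 against week 1 (15565 genes). The biological coefficient of variation was 0.304 and 0.276. Log2 changes are given ± SE. The contrasts were each adapted and each acute group against the week-12 controls, adapted against acute for each drug arm, the interaction of both drugs in each experiment, and the controls of week 12 against week 1.

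There were 39 gene lists, each named in the text with its result, and 38 of them were tested at week 12, since a list needed 3 measured genes. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data and with fry. With the estimated correlation, 0 of the 122 camera calls over all 12 comparisons held. With fry, which asks whether the genes of a list move one way, 102 of the 122 were lost and 17 other lists were called. A list's median and mean are of its genes' log2 changes. Counts "adjusted over the list alone" repeat the gene test's adjustment within a list. Chromosome values are medians over genes with an average log2 CPM of at least 3, with a prior count of 2.

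Named genes followed a rule. In comparisons with controls it took the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted genes and pseudogenes; 5 and 5 were taken in the other comparisons. It added up to 4 called members per list with the smallest adjusted p, and always Egfr, Kras, Dck, Slc29a1, Rrm1, Rrm2, Cda, Cdkn1a, Trp53, Mki67 and Krt19. A gene named for a comparison could be given for other comparisons too. The tests, lists, this rule and the alternatives below were fixed before the data were examined, except where the text says otherwise.

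Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma on log2(TPM + 1), a fit of only the groups in the contrast, a fit of all 33 libraries and leaving out each library in turn. Added after the data were seen were surrogate variables (sva 3.50.0, 3 variables), the 12 control and acute libraries with and without a culture set term, the 21 week-12 libraries with such a term, and week-1 counts summed per cluster. An undecided test of p53 activation was replaced, after its result was seen, by the test of a difference between the 2 experiments. A test of random gene sets in the 6 libraries picked for a low chromosome 4 median was replaced, after its result was seen, by the same test over all 9 adapted libraries. To compare adapted and acute changes, 20 simulations drew unchanged groups against the same controls. A floor of 3 counts over the group was used where a group had 0 counts; it covers counting error only.

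The gene test was tested on simulated data for the acute combination against controls, with 15888 genes of which 200 were changed. It recovered 14.9% of genes changed by 1.5-fold, 62.7% at 2-fold and 93.9% at 4-fold, with 8 of 122 calls false. For week 12 against week 1, with 15565 genes, it recovered 50.7%, 83.6% and 90.9%, with 9 of 159 false. The simulated libraries had no clusters or culture sets, unlike the real ones, so real recovery and false calls may differ. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.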

Results

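Messenger RNA levels were measured in 33 libraries of mP4, a mouse pancreatic organoid line that carries a mutant Kras allele and is labelled as coming from pancreatic intraepithelial neoplasia (PanIN), a precursor lesion of pancreatic cancer. The organoids, labelled as pancreatic ductal cells, grew at pH 7.4 in domes of Matrigel, a basement membrane extract. The series asks how adaptation to stress goes with drug resistance, and this part used erlotinib, which blocks the kinase of the epidermal growth factor receptor (Egfr), and gemcitabine, a deoxycytidine analog that interferes with DNA synthesis. In the adaptation experiment, cultures were brought to 10 nM of erlotinib, gemcitabine or both by steps of 1 nM per week over 12 weeks, with 3 libraries per drug arm. Controls without drug gave 12 libraries at week 1 and 3 libraries at week 12. In a separate acute experiment, control organoids received 10 nM of erlotinib, gemcitabine or both at week 12, with 3 libraries per treatment. The labels give 5 days of treatment for every sample, so the exposure just before RNA extraction is not clear for the adapted arms. Total counts per library lay between 38000470 and 39875124, and 18267 to 20642 genes had a count. Mitochondrially encoded genes, which serve as a sign of RNA and cell quality, took 2.93% to 11.63% of the counts over all libraries and 4.83% to 5.7% in the week-12 controls. Nothing in the labels says that libraries of one group came from separate cultures, so p-values measure the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise.

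Week-1 and week-12 libraries lay further apart than the drug groups did, and week and batch cannot be told apart. The first principal component held 52.7% of the variance and set the week-1 controls, at -124.82 to -67.94, apart from all week-12 libraries, at 18.8 to 74.31. The week-1 controls formed 3 clusters of 4 libraries, with correlations of 0.9872 to 0.9921 across genes within a cluster and 0.9607 to 0.9824 between clusters. In accession order the libraries went through clusters 1, 2 and 3 in turn, again and again. Among the 12 control and acute libraries of week 12, deviations from the group means fell into 3 sets, each with 1 control and 1 library of each acute treatment. The mean correlation within these sets was 0.56, against 0.30 for the next best of 216 possible assignments. The labels name no such sets, but the sets follow the accession order within each of the 4 groups. They are called culture sets here, and values within them stand beside the acute results. As the sets were found by matching deviations from group means, differences within a set are drawn toward the difference of the groups. Their spread over sets can therefore be too small.

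**Figure D1:**
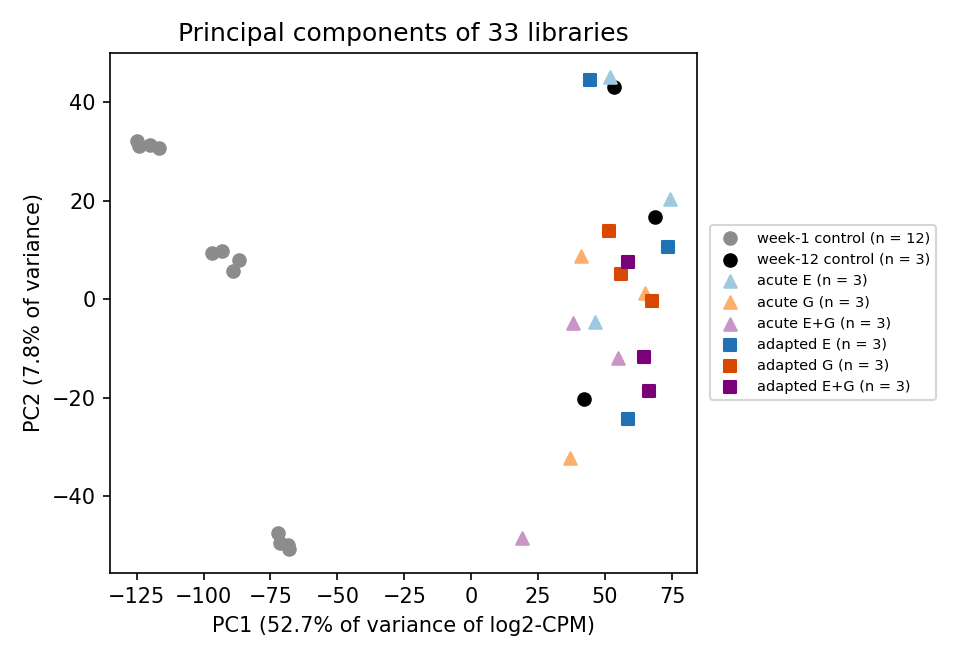
Principal component 1 (x axis, 52.7% of variance) against principal component 2 (y axis, 7.8% of variance) of log2 counts-per-million, with each point 1 of 33 libraries coloured by group. The 12 week-1 controls lie at -124.82 to -67.94 on the first component in 3 clusters of 4, and the week-12 libraries at 18.8 to 74.31.

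The first comparison asked how the control organoids themselves changed between week 1 and week 12 without drug. Proliferation genes were far lower at week 12. All 27 genes of the S phase and DNA replication list fell, with a median log2 change of -2.56, and all 21 genes of the G2 and mitosis list fell, with a median of -3.03. Rrm2, the regulated subunit of ribonucleotide reductase, fell from 275 ± 20.4 (SD, n = 12) to 18.1 ± 9.69 (SD, n = 3) counts-per-million (CPM), a log2 change of -3.90 ± 0.238 (SE). Mki67, the gene of the Ki-67 proliferation antigen, fell from 1100 ± 88.9 to 78.0 ± 85.4 CPM, and Ccne1, which encodes cyclin E1, fell from 48.6 ± 7.83 to 4.79 ± 1.23 CPM. Genes of inflammation rose in the same comparison: 18 of 19 measured members of the NF-kB and inflammatory cytokine list were higher and 1 was lower, with a median log2 change of 2.68.

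The edgeR quasi-likelihood test called 4758 genes higher and 4852 lower at week 12 among 15565 tested, and 4023 of these changed by more than 2-fold. Camera with a preset correlation called the S phase list (adjusted p = 9.06e-16; adjusted p = 0.335 with an estimated correlation), the mitosis list (adjusted p = 1.59e-11; 0.361 as the adjusted p with an estimated correlation) and the NF-kB list (adjusted p = 1.96e-06; adjusted p = 0.361 with an estimated correlation). The week-1 libraries lay in 3 clusters, and with their counts summed per cluster, as 3 sums against 3 libraries, the test called 6641 genes, of which 6455 were among the 9610. Of the 164 called values of named genes in this comparison, 15 lost their call with these sums. The SDs with n = 12, the SEs and the adjusted p of this comparison take the week-1 libraries as separate samples. They can be too small, since libraries of a cluster may be repeats of a culture. Fry called 29 of the 39 lists in this comparison, with the 12 week-1 libraries taken as separate samples. The share of mitochondrially encoded counts was 5.51% to 11.63% at week 1 and 4.83% to 5.7% at week 12.

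Among genes with the largest rises at week 12 were Csf2, the gene of the cytokine GM-CSF, and Lcn2, which encodes the iron-siderophore binding protein lipocalin 2. Csf2 rose from 1.94 ± 1.29 to 168 ± 75.0 CPM, with a log2 change of 6.47 ± 0.395 (adjusted p = 3.79e-09). Lcn2 rose from 24.7 ± 17 to 1530 ± 959 CPM, with a log2 change of 5.97 ± 0.485 (adjusted p = 6.2e-08). Csf1r, the receptor of macrophage colony-stimulating factor, rose from 0.966 ± 0.323 to 44.2 ± 10.2 CPM. Csf2 and Csf1r share 12% and 15.1% of their exonic length with another annotated gene, so their counts are uncertain to that extent. On the log2 scale, the ganglioside synthase gene St8sia1 rose by 6.22 ± 0.533, Vat1l by 6.01 ± 0.773 and the adhesion receptor gene Adgrf1 by 5.66 ± 0.394. The acyl-CoA synthetase gene Acsbg1 rose by 5.57 ± 0.412 and Cyp4a12b by 5.55 ± 0.551. Among the NF-kB list, Nfkbia, which encodes the inhibitor of NF-kB, rose by 2.69 ± 0.154 and Csf1 by 2.68 ± 0.188.

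The largest falls were of genes that were close to absent at week 12. The imprinted noncoding RNA Rian had 0 counts in all 3 week-12 controls, so its week-1 mean lay at least 268-fold above a floor of 3 counts over the group, but its counts at week 1 ranged from 7 to 840 per library and the fold rests on the libraries with high counts. Its neighbour Meg3 went from 15.1 ± 20.3 to 0.0352 ± 0.0609 CPM (log2 change -8.64 ± 2.75, adjusted p = 0.0127), with a spread at week 1 as large as its mean. The other large falls, on the log2 scale, were of the homeobox gene Rhox5 (-7.89 ± 2.02), the transcription factor gene Myb (-7.49 ± 0.929) and the aryl hydrocarbon receptor target Cyp1b1 (-7.38 ± 1.16). The guanylin receptor gene Gucy2c (-7.23 ± 2.01), Acp5 (-6.10 ± 1.03) and the aldehyde dehydrogenase gene Aldh3a1 (-6.09 ± 0.668) also fell. These sizes rest on few counts at week 12. The endocrine marker Chga and the intestinal gene Guca2a also had 0 counts in all 3 week-12 controls, and were at least 8.04-fold and at least 13.2-fold lower against the same floor.

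DNA repair genes fell with the cell cycle genes: 26 of 27 were lower and 1 was higher, with a median log2 change of -2.61 (camera adjusted p = 8.48e-13; adjusted p = 0.335 with an estimated correlation). The single-stranded DNA binding subunits Rpa1 and Rpa2 fell by 2.04 ± 0.0948 and 2.63 ± 0.155, the mismatch repair gene Msh6 by 1.19 ± 0.0672 and Xrcc2 by 2.61 ± 0.183. In the list of nucleoside uptake and metabolism, 14 of 23 genes fell and 3 rose, with a median of -0.60 (adjusted p = 0.00218; adjusted p = 0.335 with an estimated correlation). Dck, the kinase that activates gemcitabine, fell from 30.0 ± 3.22 to 6.49 ± 0.696 CPM (log2 change -2.18 ± 0.115, adjusted p = 1.02e-09). The enzyme genes Rrm1, Tk1 and Dut fell by 2.69 ± 0.181, 2.11 ± 0.12 and 2.43 ± 0.135, and the nucleoside transporter gene Slc29a1 by 1.18 ± 0.189. The cytidine deaminase gene Cda changed by -0.24 ± 0.418 (adjusted p = 0.642).

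Egfr and the lists of MAPK output, TGF-beta targets and YAP targets were higher at week 12, while the list of ErbB receptors and ligands was not called. Egfr, the target of erlotinib, rose from 96.5 ± 13.8 to 278 ± 97.6 CPM, a log2 change of 1.55 ± 0.158 (adjusted p = 6.04e-07). Of the 22 genes of MAPK pathway output, 15 rose and 1 fell, with a median of 0.85 (adjusted p = 0.00129; adjusted p = 0.335 with an estimated correlation). Among them Fos rose by 1.47 ± 0.12 and the ETS factor gene Etv1 by 2.19 ± 0.199. TGF-beta targets rose in 12 of 16 cases with a median of 1.47 (adjusted p = 2.51e-05; adjusted p = 0.335 with an estimated correlation). Tgfb2 rose by 2.82 ± 0.271 and the integrin gene Itgb6 by 1.61 ± 0.113. Of the YAP and TEAD targets, 12 of 14 rose, with a median of 0.68 (adjusted p = 0.0032; adjusted p = 0.361 with an estimated correlation), Ankrd1 by 1.60 ± 0.206. Kras rose by 0.29 ± 0.0887 (adjusted p = 0.0101), a change that was -0.10 on the log2(TPM + 1) scale. Cdkn1a, the gene of the cell cycle inhibitor p21, rose by 0.48 ± 0.158 (adjusted p = 0.0154). Trp53 and the ductal keratin gene Krt19 did not pass the test, at -0.14 ± 0.129 and -0.34 ± 0.246 (adjusted p = 0.379 and 0.238).

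Genes of 4 metabolic lists were lower at week 12. In the oxidative phosphorylation list 23 of 24 genes fell, with a median of -0.64 (adjusted p = 3.22e-08; adjusted p = 0.361 with an estimated correlation). Among them were the genes of cytochrome c (Cycs, -1.87 ± 0.132) and an ATP synthase subunit (Atp5b, -1.12 ± 0.0995). Cholesterol synthesis genes fell in 16 of 21 cases and 1 rose (median -0.77, adjusted p = 0.000841; adjusted p = 0.455 with an estimated correlation). Hmgcr, which encodes the rate-limiting reductase, changed by -0.97 ± 0.136. Of 15 fatty acid synthesis genes 10 fell and 1 rose (median -0.93, adjusted p = 0.0119; adjusted p = 0.361 with an estimated correlation). Fasn changed by -1.31 ± 0.128 and Elovl6 by -2.56 ± 0.217. NRF2 targets fell in 12 of 20 cases and 1 rose (median -0.59, adjusted p = 0.00764; adjusted p = 0.361 with an estimated correlation). The pentose phosphate genes Tkt and Pgd fell by 1.3 ± 0.0974 and 1.39 ± 0.105.

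**Figure D2:**
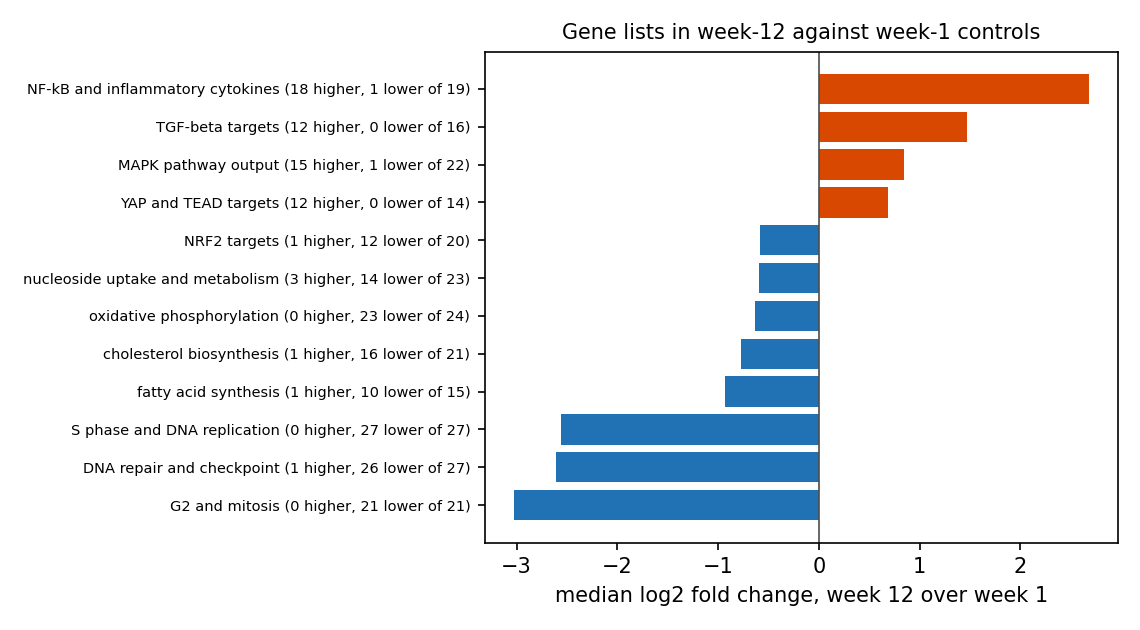
Median log2 change from week-1 to week-12 controls (x axis) of the 12 gene lists that camera called with the preset correlation, as bars, with the number of members called higher and lower beside each. The G2 and mitosis list is lowest at -3.03 and the NF-kB and inflammatory cytokine list highest at 2.68.

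The remaining 27 lists were not called by camera at week 12 against week 1. Counts of members higher and lower were 6 and 3 of 14 for ErbB receptors and ligands, 11 and 6 of 26 for p53 targets, 3 and 3 of 10 for ABC drug efflux transporters and 1 and 12 of 20 for xenobiotic and aldehyde metabolism. They were 8 and 1 of 19 for interferon-stimulated genes, 7 and 2 of 15 for MHC class I antigen presentation, 5 and 2 of 22 for hypoxia and glycolysis and 4 and 8 of 19 for pH regulation. The hypoxia list holds 21 symbols but 22 tested gene identifiers, since a symbol can match more than 1 identifier. Further counts were 13 and 6 of 22 for the integrated stress and unfolded protein response, 7 and 4 of 16 for senescence, 8 and 2 of 19 for the BCL2 and IAP families and 10 and 3 of 22 for lysosome and autophagy. Wnt targets had 2 and 6 of 16, the Notch pathway 6 and 0 of 12, ductal epithelium 8 and 2 of 18 and gastric and PanIN-type epithelium 1 and 13 of 23. Intestinal epithelium had 1 and 6 of 11, basal and squamous epithelium 5 and 7 of 17 and the mesenchymal state 3 and 0 of 11. Single members changed strongly: the bicarbonate transporter gene Slc4a4 rose by 2.77 ± 0.181, the proapoptotic gene Bmf by 3.51 ± 0.346, the tight junction gene Cldn4 by 2.58 ± 0.186 and the squamous marker Sprr1a by 5.43 ± 0.623. The pancreatic transcription factor gene Pdx1 fell by 1.39 ± 0.222 and the aryl hydrocarbon receptor target Cyp1a1 by 6.42 ± 0.798.

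Markers of other cell types were sparse and mixed. For tuft cells 6 of 10 measured genes rose and 0 fell, with Dclk1 at 2.45 ± 0.521. For fibroblasts 2 of 3 rose, Col1a1 by 2.14 ± 0.52 and Pdgfra by 2.08 ± 0.71. For immune cells 3 of 5 rose and 2 fell, and the abundant marker Cd74 went from 0.236 ± 0.0738 to 1.1 ± 0.972 CPM. For endothelial cells 2 rose, Flt1 by 3.17 ± 0.388 and Vwf by 1.56 ± 0.358, and 1 of 5 fell. Acinar genes had 1 higher and 1 lower of 4, with a list median of 0.42 and a mean of -0.65, and 2 of 3 endocrine genes fell. Of 23 ribosomal protein genes 7 rose and 1 fell, and of 13 mitochondrially encoded genes 5 fell and 0 rose, mt-Nd1 by 0.75 ± 0.181.

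Acute treatment with erlotinib and gemcitabine together changed more genes than any other drug arm did against the week-12 controls. Cell cycle genes were higher: Rrm2 rose from 18.1 ± 9.69 CPM in the week-12 controls to 79.1 ± 47.5 CPM (SD, n = 3 each), a log2 change of 2.12 ± 0.447 (SE). Tk1, thymidine kinase 1, rose from 19.4 ± 5.28 to 66.2 ± 27.0 CPM, a change of 1.76 ± 0.323. Dck rose from 6.49 ± 0.696 to 16.1 ± 5.79 CPM, a change of 1.31 ± 0.295 (adjusted p = 0.0258). Of the genes of feedback on growth factor signalling, Spry4 fell from 33.5 ± 8.48 to 14 ± 6.03 CPM and Spry2 from 97.6 ± 6.21 to 60.3 ± 4.68 CPM, and both encode Sprouty inhibitors of receptor tyrosine kinases. These levels of Rrm2 and Dck still lay below the 275 ± 20.4 and 30.0 ± 3.22 CPM of the week-1 controls.

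The edgeR test called 287 genes higher and 263 lower of 15888 tested, 187 of them by more than 2-fold. On log2(TPM + 1) the balance turned, with 268 higher and 357 lower and 367 of the 550 shared. The number rests on few libraries: without acute combination replicate 2 it was 16, without week-12 control replicate 1 it was 38, without control replicate 3 it was 70 and without acute combination replicate 1 it was 130. With a culture set term in a fit of the 12 control and acute libraries it was 3566, against 361 without the term. Fitting only the 2 groups of the contrast gave 0 calls. The acute libraries come from another experiment than the controls, so drug and experiment cannot be told apart in single comparisons of acute treatment with controls. For the cell cycle lists acute erlotinib, from the same experiment as the other acute libraries, serves as a further comparison, with a mean mitosis median within sets of 0.04 ± 0.58 against 1.85 ± 0.76 after gemcitabine and 2.24 ± 0.71 after both (SD over 3 sets).

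Genes of replication and repair were among the largest rises with the combination. Mybl2, a transcription factor of cell cycle genes, rose from 5.03 ± 2.48 to 24.7 ± 13.2 CPM, a log2 change of 2.29 ± 0.417 (adjusted p = 0.0149). Brca1, which acts in homologous recombination, rose from 4.11 ± 3.29 to 21.4 ± 11.1 CPM, a change of 2.38 ± 0.605 (adjusted p = 0.0419). The Fanconi anaemia gene Fanca, uncertain because it shares 10.5% of its exonic length, rose by 2.31 ± 0.53, the replication initiation gene Ticrr by 2.22 ± 0.553 and the histone chaperone gene Asf1b by 2.19 ± 0.546. The protocadherin gene Pcdh10 rose by 2.32 ± 0.615 and BC030867 by 2.68 ± 0.7. The histone gene Hist1h2ap rose by 3.06 ± 0.657, but it belongs to a family of near-identical genes and shares 28.6% of its exonic length, so its value is uncertain. The largest falls were of Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1 (-2.53 ± 0.621), Adgrf1 (-2.48 ± 0.476), Tmcc3 (-1.80 ± 0.417) and the tissue factor gene F3 (-1.71 ± 0.436). Next came the Ras GTPase-activating gene Rasa4 (-1.68 ± 0.43), the retinol dehydrogenase gene Rdh10 (-1.63 ± 0.314), Hpcal4 (-1.62 ± 0.382) and Spry4 (-1.26 ± 0.315).

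In the S phase and DNA replication list 8 of 27 genes rose over all genes tested and 25 adjusted over the list alone, with a median of 1.27 (camera adjusted p = 1.7e-15; adjusted p = 0.551 with an estimated correlation). Ccne1 rose by 1.61 ± 0.331, the transcription factor gene E2f1 by 1.27 ± 0.275, the helicase subunit gene Mcm7 by 1.18 ± 0.264 (uncertain, with 12.6% of its exonic length shared) and Uhrf1, which maintains DNA methylation, by 1.65 ± 0.381. In the G2 and mitosis list 1 of 21 genes rose, Cdk1 by 1.59 ± 0.418, and 20 rose adjusted over the list alone, with a median of 1.86 (adjusted p = 6.51e-16; adjusted p = 0.551 with an estimated correlation). Mki67 did not pass the test, at 2.03 ± 0.775 (adjusted p = 0.146). Of 27 repair and checkpoint genes 7 rose, and 19 adjusted over the list alone, with a median of 1.3 (adjusted p = 5.93e-12; adjusted p = 0.551 with an estimated correlation). Xrcc1, which encodes a scaffold of single-strand break repair, rose from 39.4 ± 2.14 to 69.2 ± 13.7 CPM, and on the log2 scale the checkpoint kinase gene Chek2 rose by 1.3 ± 0.292 and the Brca1 partner gene Bard1 by 2.08 ± 0.47. The nucleoside list had 4 of 22 genes higher, Tk1, Rrm2, Dck and Dut (1.16 ± 0.259), and 7 adjusted over the list alone, with a median of 0.07 (adjusted p = 0.0265; adjusted p = 0.551 with an estimated correlation). Within the 3 culture sets, the S phase medians were 1.18, 1.40 and 1.03 and the mitosis medians 2.65, 1.42 and 2.66, each treated library against the control of its set.

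MAPK pathway output was lower with the combination. Spry2, Spry4 and the ERK phosphatase gene Dusp4 (-0.93 ± 0.246) were the 3 called of 22 genes, also adjusted over the list alone, with a median of -0.33 (adjusted p = 0.0249; adjusted p = 0.653 with an estimated correlation). In the ErbB list Errfi1, a feedback inhibitor of Egfr, fell from 395 ± 27.8 to 233 ± 48.4 CPM as 1 of 14 genes, 3 adjusted over the list alone, with a median of -0.33 (adjusted p = 0.0265; adjusted p = 0.551 with an estimated correlation). The NF-kB list had a median of -1.18 with 0 of 20 genes called (adjusted p = 5.64e-05; adjusted p = 0.647 with an estimated correlation). Within sets its medians were -1.5, -1.26 and -0.78, and those of the MAPK list were -0.47, -0.28 and -0.13. Lists with smaller shifts were called higher for oxidative phosphorylation (0.14, adjusted p = 0.014), cholesterol synthesis (0.22, 0.0265), fatty acid synthesis (0.25, 0.0265) and mitochondrially encoded genes (0.45, 0.0265), with adjusted p of 0.703 to 0.761 with an estimated correlation. Lists called lower were the integrated stress response (-0.47, adjusted p = 0.00933), Wnt targets (-0.56, 0.0265), TGF-beta targets (-0.52, 0.0265) and ribosomal proteins (-0.20, 0.0265), with adjusted p of 0.647 to 0.761 with an estimated correlation. The share of mitochondrially encoded counts was 6.31% to 7.63%, above the 4.83% to 5.7% of the controls.

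Single called members of other lists were the proapoptotic gene Bcl2l11, which fell by 0.86 ± 0.158, Slc4a4 (-0.96 ± 0.197), the Notch target Hes1 (-0.74 ± 0.181) and coactivator Maml2 (-0.64 ± 0.137), and the autophagy gene Wipi1 (-0.45 ± 0.117). The retinal dehydrogenase gene Aldh1a1 rose by 1.93 ± 0.431, the mesenchymal transcription factor gene Snai1 by 2.00 ± 0.463, the glycolytic gene Eno1 by 0.68 ± 0.173, Cox6a1 by 0.65 ± 0.157, the lipogenic regulator Mlxipl by 0.78 ± 0.203 and Spp1 by 1.32 ± 0.336, the last uncertain with 18.8% of its exonic length shared. Egfr (0.15 ± 0.313, adjusted p = 0.841), Kras (-0.56 ± 0.18, 0.0859), Rrm1 (1.39 ± 0.38, 0.054), Slc29a1 (0.04 ± 0.196, 0.94), Cda (-0.07 ± 0.381, 0.938), Cdkn1a (-0.25 ± 0.278, 0.662), Trp53 (0.19 ± 0.196, 0.646) and Krt19 (-0.60 ± 0.527, 0.569) did not pass the test. Of the 26 p53 targets 0 were called by edgeR and 9 lay above 0.

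**Figure D3:**
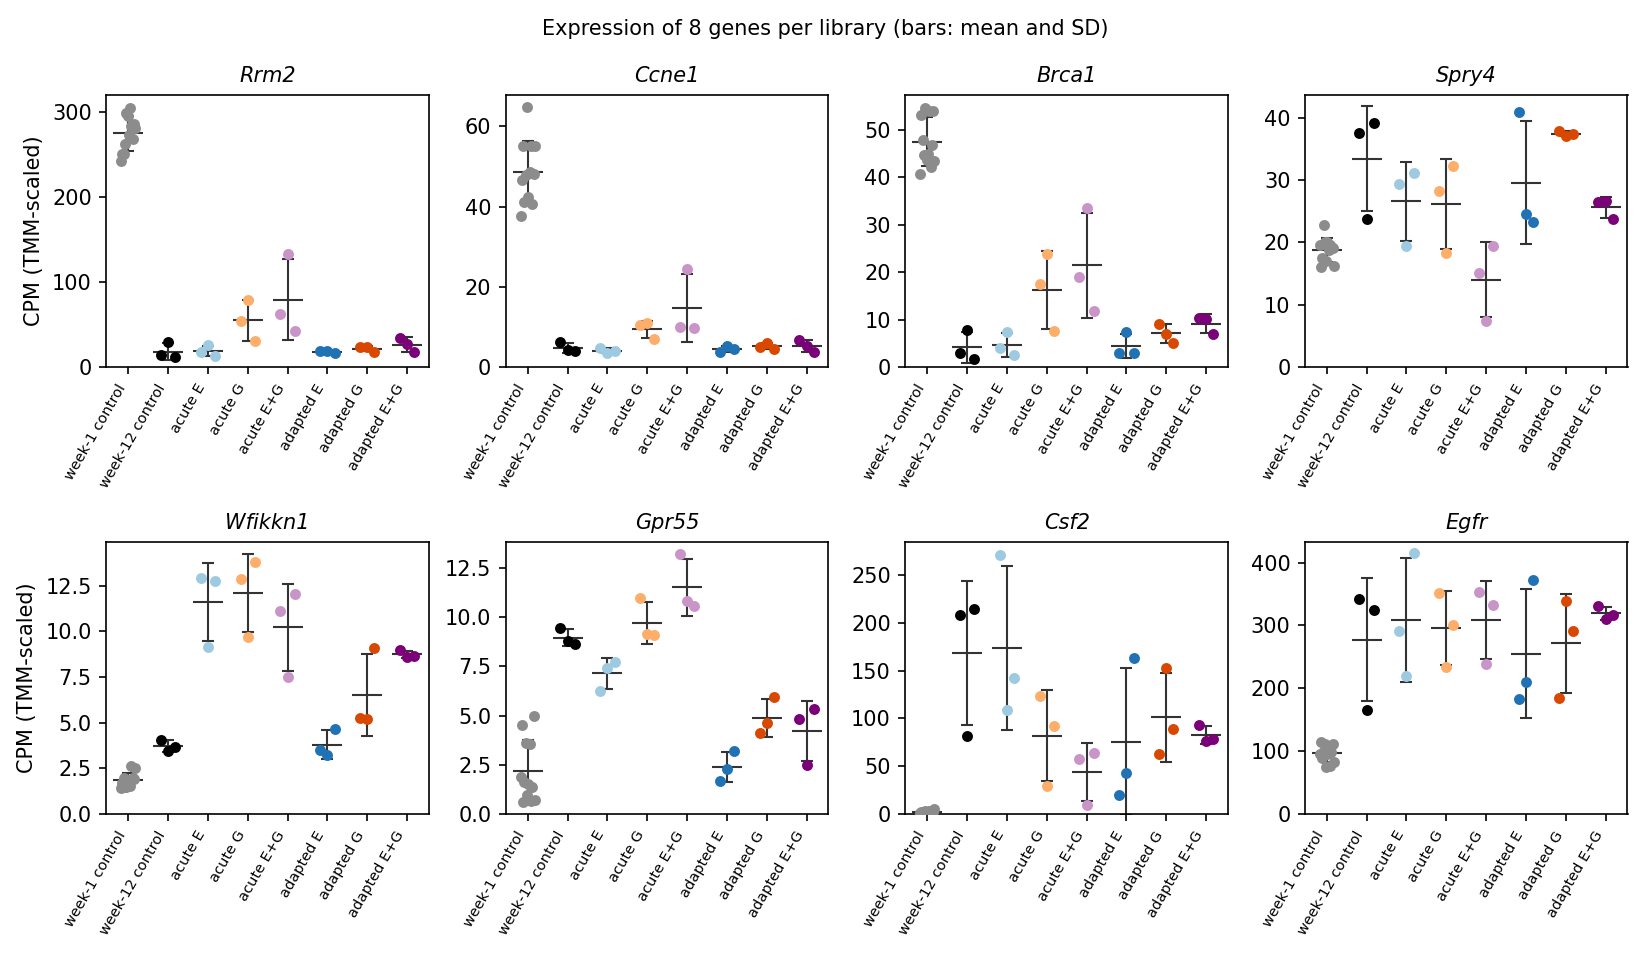
Counts-per-million, TMM-scaled (y axis of each panel), of Rrm2, Ccne1, Brca1, Spry4, Wfikkn1, Gpr55, Csf2 and Egfr in the 8 groups, with points for libraries and bars of mean and SD (n = 12 for week-1 controls, n = 3 otherwise). Rrm2 averages 275 at week 1, 18.1 in week-12 controls and 79.1 after the acute combination, and Gpr55 averages 8.96 in week-12 controls and 2.39 after adaptation to erlotinib.

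Acute gemcitabine alone shifted the cell cycle lists upward, with no called member over all genes in the fit without culture sets. Rrm2 had 54.8 ± 24.3 CPM against 18.1 ± 9.69 in controls (SD, n = 3 each), a change of 1.60 ± 0.44 that did not pass the test (adjusted p = 0.188), and Dck had 12.8 ± 4.89 against 6.49 ± 0.696 CPM (0.97 ± 0.293, adjusted p = 0.226). In the S phase list 0 of 27 genes were called over all genes and 8 rose adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.75e-12; adjusted p = 0.825 with an estimated correlation). The mitosis list had a median of 1.47 (adjusted p = 1.72e-17; adjusted p = 0.825 with an estimated correlation) with 0 of 21 called in either way. The repair list had a median of 0.94 with 8 genes higher adjusted over the list alone (adjusted p = 1.01e-10; adjusted p = 0.825 with an estimated correlation). Within the culture sets, the S phase medians were 1.18, 0.81 and 0.73 and the mitosis medians 2.29, 0.98 and 2.29. With a culture set term in the fit of 12 libraries, 20 of 27 S phase, 20 of 21 mitosis and 16 of 27 repair genes were called higher. The share of mitochondrially encoded counts was 5.93% to 7.48%, above the 4.83% to 5.7% of the controls.

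The edgeR test called 7 genes higher and 6 lower after acute gemcitabine. Wfikkn1, which encodes a secreted protein that binds growth and differentiation factors, rose from 3.72 ± 0.303 to 12.1 ± 2.15 CPM (1.71 ± 0.242, adjusted p = 0.0128). Atp6v0a1, a subunit of the proton pump of acidic organelles, rose by 0.72 ± 0.112, the sodium-proton exchanger gene Slc9a5 by 0.96 ± 0.169 and Lmntd2 by 0.76 ± 0.127. Sprtn, a protease that clears DNA-protein crosslinks, fell by 0.72 ± 0.124, the nuclear import gene Kpna4 by 0.60 ± 0.103, the zinc finger gene Zfp655 by 0.67 ± 0.117 and Aaed1 by 0.87 ± 0.145. Sprtn and Aaed1 share 10.4% and 13.1% of their exonic length with another gene and are uncertain. Leaving out week-12 control replicate 1 or 3 or acute gemcitabine replicate 1 or 3 left 0 genes called, and leaving out gemcitabine replicate 2 left 4. The term for culture sets changed the number to 1296, against 7 in the same 12 libraries without it. DESeq2 called 208, and 1791 genes had an unadjusted p under 0.05.

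Smaller list shifts after acute gemcitabine were nucleoside metabolism (0.16, adjusted p = 0.0316, 4 genes adjusted over the list alone) and fatty acid synthesis (0.20, adjusted p = 0.0316) on the higher side, with adjusted p of 0.825 and 0.922 with an estimated correlation. On the lower side were the NF-kB list (-0.61, adjusted p = 0.0311) and ribosomal proteins (-0.28, adjusted p = 7.24e-06), both with an adjusted p of 0.922 with an estimated correlation. Mki67 (1.51 ± 0.763, adjusted p = 0.485), Rrm1 (1.007 ± 0.377, 0.315), Kras (-0.46 ± 0.18, 0.344), Egfr (0.09 ± 0.313, 0.96), Cdkn1a (-0.07 ± 0.278, 0.967), Trp53 (0.04 ± 0.196, 0.976), Slc29a1 (0.14 ± 0.196, 0.87), Cda (0.38 ± 0.381, 0.786) and Krt19 (-0.17 ± 0.525, 0.953) did not pass the test.

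After acute erlotinib alone 2 genes were called, and neither kept its call on log2(TPM + 1), where 1 other gene was called. Wfikkn1 (ENSMUSG00000071192, chromosome 17 at 25877628 to 25880858 of GRCm38) rose from 3.72 ± 0.303 to 11.6 ± 2.13 CPM, a log2 change of 1.64 ± 0.242 (adjusted p = 0.0242). Its level after the combination was 10.2 ± 2.39 CPM (1.45 ± 0.241, edgeR adjusted p = 0.0109), so that it was called in all 3 acute groups. Those groups share the same 3 controls, from another experiment, so this rise can also come from the experiment. The other called gene was Gm9754, at 1.37 ± 0.192 (edgeR adjusted p = 0.0242). It falls outside the rule for named genes and was chosen after its values were seen. As 61.4% of its exonic length is shared with another gene, it is uncertain. Spry4 had 26.6 ± 6.34 CPM against 33.5 ± 8.48 in controls and was not called (-0.33 ± 0.31), and Rrm2 had 18.8 ± 6.3 CPM. Mitochondrially encoded genes were called higher as a list, with a median of 0.65 (adjusted p = 1.06e-07; adjusted p = 0.97 with an estimated correlation), and their share of counts was 6.12% to 10.26%. The fixed genes, Egfr (0.15 ± 0.313), Mki67 (-0.25 ± 0.749), Dck (0.05 ± 0.292) and Kras (-0.01 ± 0.18) among them, were not called, each with an adjusted p of 1. Leaving out any of the 3 week-12 controls or acute erlotinib replicate 1 or 3 left 0 genes called by edgeR, and with the culture set term 142 were called, against 5 in the same 12 libraries without it. DESeq2 called 35, and 865 genes had an unadjusted p under 0.05.

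After adaptation to erlotinib over 12 weeks, Gpr55, the gene of a receptor for lysophosphatidylinositol, fell from 8.96 ± 0.449 CPM in week-12 controls to 2.39 ± 0.763 CPM (SD, n = 3 each). Its log2 change was -1.90 ± 0.259 (edgeR adjusted p = 0.017), and it was the 1 gene called. Gpr55 (ENSMUSG00000049608) lies on chromosome 1 at 85938318 to 85961007 of GRCm38. Genes of cholesterol synthesis lay lower as a group: all 21 were below 0, with a median of -0.54, and 0 were called over all genes but 8 adjusted over the list alone (camera adjusted p = 1.87e-15; adjusted p = 0.231 with an estimated correlation). Hmgcr was at -0.53 ± 0.167 (adjusted p = 0.494) and the low-density lipoprotein receptor gene Ldlr at -0.51 ± 0.14 (adjusted p = 0.418). Neither gene was called here or picked by the rule for named genes in this comparison. Egfr was not called, at -0.12 ± 0.313 (adjusted p = 0.968). The single call was lost without any 1 of the 3 controls or adapted erlotinib replicate 1 or 2, and 13 genes were called without replicate 3. With all 33 libraries in a fit Gpr55 lost its call and 8 other genes were called, and with a culture set term in the fit of 21 libraries 25 were called, Gpr55 among them. The share of mitochondrially encoded counts was 5.96% to 6.94%, above the 4.83% to 5.7% of the controls. DESeq2 called 72, and 1103 genes had an unadjusted p under 0.05.

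Other lists called after adaptation to erlotinib were xenobiotic and aldehyde metabolism (0.55, adjusted p = 0.000331, 4 genes adjusted over the list alone), 4 fibroblast genes (0.63, 0.0413, 1 adjusted over the list alone) and ribosomal proteins (0.16, 0.0413) on the higher side. Their adjusted p with an estimated correlation was 0.134, 0.231 and 0.775. On the lower side were the NF-kB list (-1.06, adjusted p = 1.22e-07, 1 gene adjusted over the list alone), G2 and mitosis (-1.06, 0.00128), MHC class I (-0.39, 0.00394), fatty acid synthesis (-0.25, 0.00128), the integrated stress response (-0.24, 0.00491) and hypoxia (-0.20, 0.00858). Epithelial lists on this side were ductal (-0.30, 0.0173), gastric and PanIN-type (-0.40, 0.0413) and basal epithelium (-0.35, 0.00344), and MAPK output was at -0.24 (0.0463). With an estimated correlation, the adjusted p was 0.231 for the ductal list and 0.523 to 0.697 for the other lists of this side. Without week-12 control replicate 2 the mitosis median was 0.21, and without adapted replicate 1 the ribosomal median was -0.04. Mki67 (-1.19 ± 0.76, adjusted p = 0.805), Rrm2 (0.00 ± 0.433, 1), Dck (0.06 ± 0.292, 0.978), Kras (-0.04 ± 0.18, 0.979) and Cdkn1a (0.01 ± 0.278, 0.997) did not pass the test.

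Adaptation to gemcitabine gave 0 called genes by edgeR, where 914 genes had an unadjusted p under 0.05 and DESeq2 called 31. Rrm2 had 21.4 ± 3.16 CPM against 18.1 ± 9.69 in controls (0.23 ± 0.432, adjusted p = 0.988) and Dck was at 0.27 ± 0.292 (adjusted p = 0.976). Gpr55 had 4.87 ± 0.954 CPM and was not called (-0.89 ± 0.251, adjusted p = 0.627). Slc29a1 (-0.09 ± 0.196, 0.988), Rrm1 (0.28 ± 0.374, 0.985), Cda (-0.16 ± 0.381, 0.989), Egfr (-0.04 ± 0.313, 0.995) and Mki67 (-0.21 ± 0.748, 0.995) did not pass either. Interferon-stimulated genes had a median of 1.99 with 16 genes higher adjusted over the list alone (camera adjusted p = 0.000508; adjusted p = 0.923 with an estimated correlation). Their library medians were 3.37 in replicate 2 against -0.34 and -0.22, and without replicate 2 the median was -0.38.

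Cholesterol synthesis was called lower after adaptation to gemcitabine (median -0.28, camera adjusted p = 0.000247, and 0.923 with an estimated correlation). All arms were set against the same 3 week-12 controls, so a list that recurs across arms is not separate evidence. Lists called higher were S phase (0.39, adjusted p = 0.000508), repair (0.23, 0.0106), ABC transporters (0.29, 0.0106) and xenobiotic metabolism (0.52, 0.0175, 1 gene adjusted over the list alone), with adjusted p of 0.623 to 0.923 with an estimated correlation. The G2 and mitosis list was called higher (adjusted p = 0.0378; adjusted p = 0.923 with an estimated correlation), though its median was 0.02 and its mean -0.03, and without control replicate 3 the median was -0.39. The NF-kB list (-0.60, adjusted p = 0.0106), hypoxia (-0.13, 0.0106), the integrated stress response (-0.20, 0.0304) and ribosomal proteins (-0.09, 0.00669) were called lower, each with an adjusted p of 0.923 with an estimated correlation. Without adapted replicate 2 the ribosomal median was 0.07.

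Adaptation to both drugs gave 0 called genes by edgeR, with 1293 genes at an unadjusted p under 0.05 and 74 called by DESeq2. Rrm2 had 26.3 ± 8.72 CPM (0.53 ± 0.433, adjusted p = 0.803), Gpr55 4.21 ± 1.51 CPM (-1.1 ± 0.252, 0.242) and Wfikkn1 8.73 ± 0.213 CPM (1.22 ± 0.24, 0.242). Egfr (0.19 ± 0.313, 0.92), Kras (-0.27 ± 0.18, 0.739) and Dck (0.12 ± 0.292, 0.949) did not pass the test. Cholesterol synthesis genes lay lower with a median of -0.52, 5 of them adjusted over the list alone (camera adjusted p = 2.04e-11; adjusted p = 0.808 with an estimated correlation), as did the integrated stress response (-0.42, adjusted p = 1.62e-06; adjusted p = 0.808 with an estimated correlation). The NF-kB list (-0.77, adjusted p = 0.00217), oxidative phosphorylation (-0.10, 0.0348) and ribosomal proteins (-0.17, 0.00115) were also called lower, each with an adjusted p of 0.893 with an estimated correlation. S phase (0.50, adjusted p = 0.000214), G2 and mitosis (0.14, 0.0171), repair (0.36, 1.09e-05), xenobiotic metabolism (0.07, 0.0348) and YAP targets (0.21, 0.0287) were called higher, with adjusted p of 0.808 to 0.893 with an estimated correlation. Without control replicate 3 the mitosis median was -0.27.

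**Figure D4:**
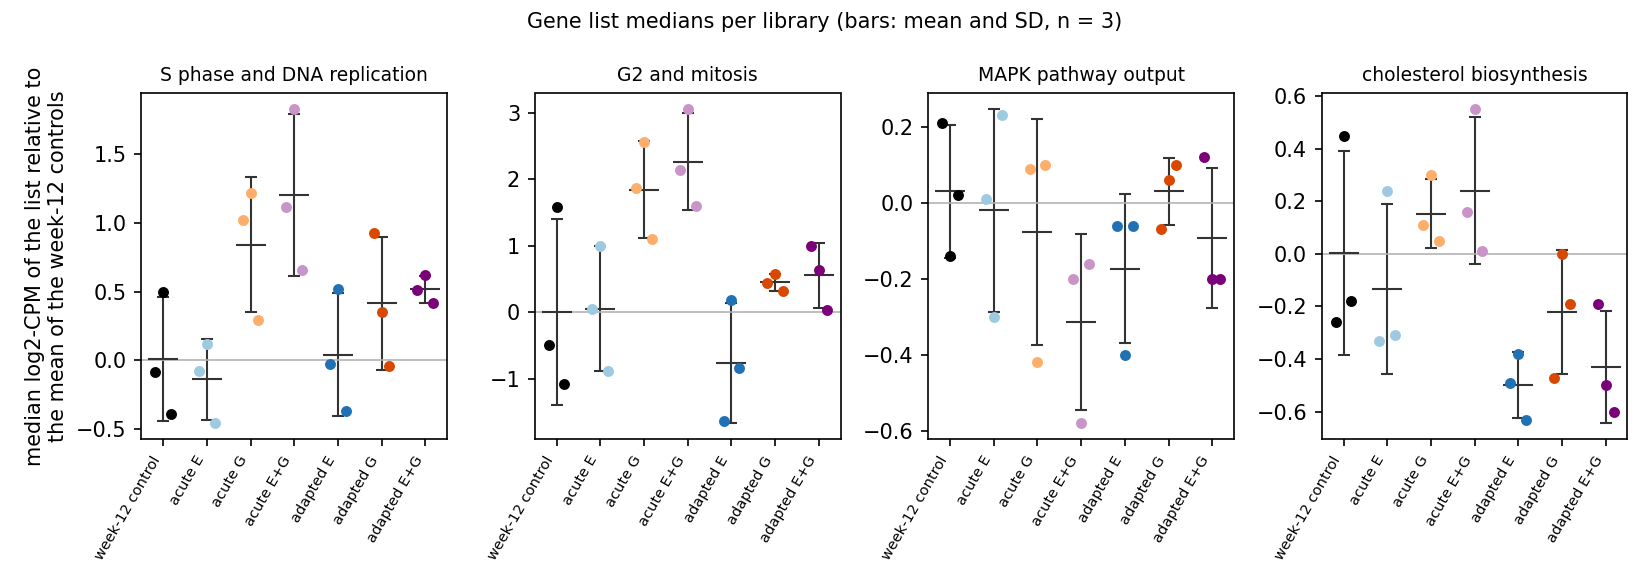
Median log2 counts-per-million of the S phase, G2 and mitosis, MAPK output and cholesterol synthesis lists in each week-12 library, relative to the mean of the week-12 controls (y axis), with points for libraries and bars of mean and SD (n = 3). The S phase list shifts by 1.27 after the acute combination and 0.91 after acute gemcitabine, and the cholesterol list by -0.54 after adaptation to erlotinib.

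Genes of chromosome 4 lay lower in 6 of the 9 adapted libraries, a feature found after the data were seen. Relative to the median of the autosomes, the chromosome 4 median was -0.38 and -0.37 in erlotinib replicates 1 and 2, -0.31 and -0.32 in gemcitabine replicates 1 and 3 and -0.17 and -0.36 in combination replicates 2 and 3. It was -0.03, 0 and -0.10 in the other 3 adapted libraries and lay between -0.02 and 0.03 in the 12 control and acute libraries of week 12. Over all 9 adapted and all 9 acute libraries the means were -0.23 ± 0.15 and 0.01 ± 0.02 (SD), and an exact two-sided permutation test over 48620 splits gave p = 0.000165, or 0.0033 adjusted over 20 chromosomes. The test treats these libraries as exchangeable, but the acute libraries fall into 3 culture sets, so its p-value can be too small. The real split is also that between the adaptation and the acute experiment. Chromosome 4 held 6.08% of the genes tested, but 28.9%, 31.1% and 25.9% of the genes lower at an unadjusted p under 0.05 after adaptation to erlotinib, gemcitabine and both. After the 3 acute treatments it held 3.35% to 5% of such genes. In adapted against acute organoids it held 17.4%, 17.4% and 13% of them for erlotinib, gemcitabine and both.

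**Figure D5:**
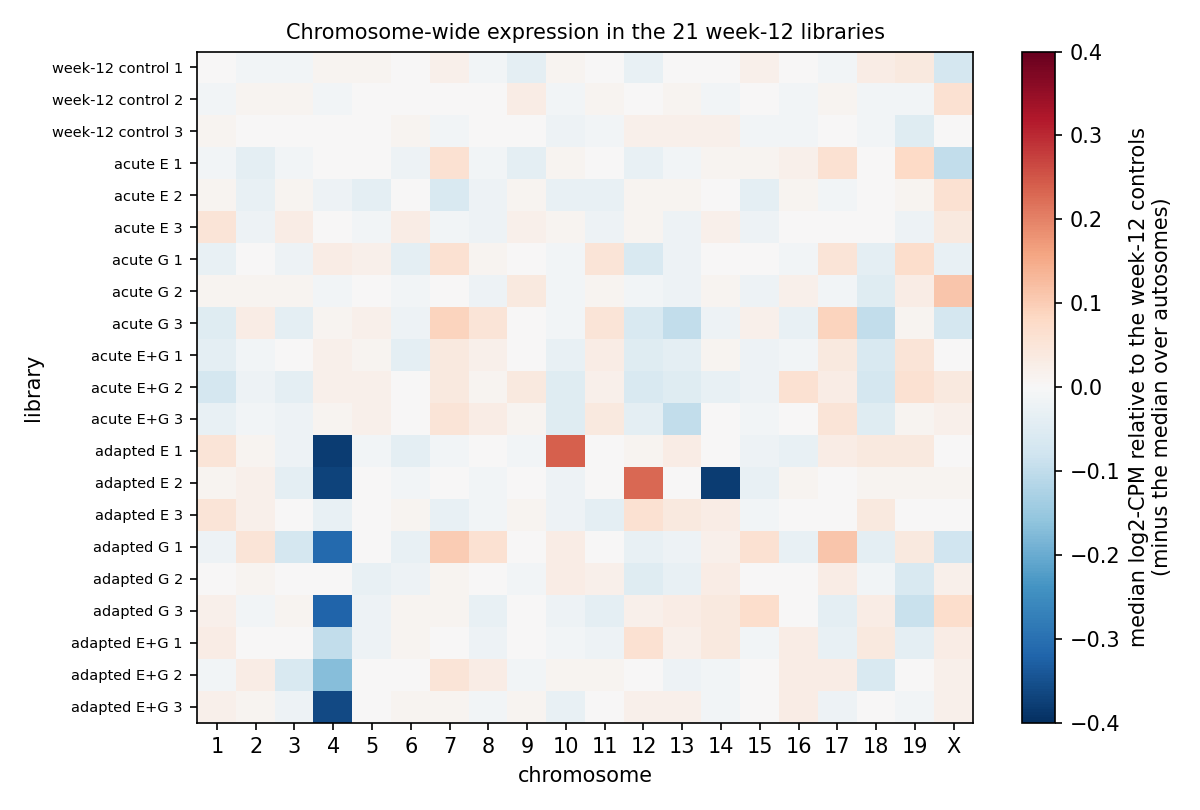
Heat map of the 21 week-12 libraries against chromosomes, coloured by the median log2 counts-per-million relative to the week-12 controls minus the median of the autosomes, on a scale of -0.4 to 0.4. Chromosome 4 lies at -0.17 to -0.38 in 6 of the 9 adapted libraries and at -0.02 to 0.03 in control and acute libraries.

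Adapted and acutely treated organoids were then compared at equal dose, which sets cultures adapted over 12 weeks against acutely treated ones and also the adaptation against the acute experiment. As the labels give 5 days for both, how the 2 exposures differed just before extraction is not known. For erlotinib, Glul, the gene of glutamine synthetase, was higher in the adapted organoids, with 93.4 ± 21.6 against 35.9 ± 2.35 CPM (SD, n = 3 each), a log2 change of 1.39 ± 0.213 (adjusted p = 0.0268). The actin-associated gene Synpo was higher by 1.40 ± 0.254, Zfp866 by 1.05 ± 0.189, Kpna4 by 0.61 ± 0.103 and Zkscan3 by 0.56 ± 0.0927. Wfikkn1 (-1.60 ± 0.242), Gpr55 (-1.57 ± 0.257), Fam167a (-1.40 ± 0.222) and Ctsh, the gene of the lysosomal protease cathepsin H (-1.09 ± 0.164), were lower. The edgeR test called 5 genes higher and 7 lower, and the further 3 were Far2, Gm9754 and Gm43863, all lower and chosen after their values were seen; they share 12.6%, 61.4% and 33.2% of their exonic length and are uncertain. Leaving out adapted replicate 1 or 2 or any of the 3 acute replicates left 0 genes called, and leaving out adapted replicate 3 gave 52; DESeq2 called 298.

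Lists called lower in erlotinib-adapted than in acutely treated organoids were NF-kB (-1.24, camera adjusted p = 1.97e-07), cholesterol synthesis (-0.35, 1.51e-06, 6 genes adjusted over the list alone), basal epithelium (-0.64, 0.000445), the integrated stress response (-0.28, 0.000802), mitochondrially encoded genes (-0.48, 0.000879), hypoxia (-0.26, 0.00127), G2 and mitosis (-0.85, 0.0069), MHC class I (-0.35, 0.0179) and gastric and PanIN-type epithelium (-0.55, 0.0271). Ribosomal proteins were called higher (0.30, adjusted p = 0.000802). With an estimated correlation, the adjusted p of these 10 lists was 0.677 to 0.806. Egfr (-0.26 ± 0.313, adjusted p = 0.766), Rrm2 (-0.05 ± 0.433, 0.974) and Mki67 (-0.95 ± 0.757, 0.626) did not pass the test.

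For gemcitabine, adapted and acute organoids differed in 0 genes by edgeR, with 1433 genes at an unadjusted p under 0.05 and 58 called by DESeq2. Rrm2 was at -1.37 ± 0.437 (adjusted p = 0.417), Dck at -0.70 ± 0.292 (0.505) and Mki67 at -1.72 ± 0.768 (0.53). As lists, S phase (-0.51, camera adjusted p = 1.43e-05), G2 and mitosis (-1.48, 9.4e-14), repair (-0.80, 6.98e-06), nucleoside metabolism (-0.20, 0.0207), cholesterol synthesis (-0.38, 4.25e-08), fatty acid synthesis (-0.58, 1.43e-05), hypoxia (-0.29, 3.32e-05) and oxidative phosphorylation (-0.12, 0.012) were called lower in the adapted organoids. Their adjusted p with an estimated correlation was 0.621 to 0.88.

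For the combination, cell cycle and cholesterol genes were lower in adapted than in acutely treated organoids. Pcsk9, a secreted regulator of the low-density lipoprotein receptor, had 185 ± 40.9 CPM after adaptation and 355 ± 41 CPM after acute treatment (-0.95 ± 0.188, adjusted p = 0.019), and the sterol synthesis gene Nsdhl had 91.3 ± 15.6 and 217 ± 42.4 CPM (-1.26 ± 0.264, adjusted p = 0.0216). Tk1 (-1.57 ± 0.321), Ccne1 (-1.50 ± 0.33) and Dck (-1.19 ± 0.294) were lower, and Errfi1 (0.72 ± 0.165) and the receptor gene Erbb3 (0.68 ± 0.168) were higher. Pcsk9 and Eno1, both lower, lie on chromosome 4, whose genes lay lower in most adapted libraries. Errfi1, which was higher, lies there too. The edgeR test called 183 genes higher and 255 lower in the adapted organoids, 124 of them by more than 2-fold. On log2(TPM + 1) the balance turned, with 415 higher and 151 lower and 264 of the 438 shared. Every one of the 6 libraries except acute replicate 3 moved this number by over 1.5 times when left out: 31, 31 and 88 without adapted replicates 1, 2 and 3, and 118 and 10 without acute replicates 1 and 2.

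The largest differences for the combination were Igsf1, an immunoglobulin superfamily gene (4.24 ± 1.04), the complement gene C3 (2.21 ± 0.521), Auts2 (2.03 ± 0.398), Ndnf (2.00 ± 0.521) and Adgrf1 (1.87 ± 0.468) on the higher side. On the lower side were the cytochrome P450 gene Cyp2d10 (-3.85 ± 0.965), Pcdh10 (-3.30 ± 0.644), Papln (-2.63 ± 0.536), the water channel gene Aqp1 (-2.37 ± 0.545) and the DNA helicase gene Recql4 (-2.21 ± 0.508). In the cholesterol list 7 of 21 genes were lower, 18 adjusted over the list alone, with a median of -0.70 (camera adjusted p = 8.95e-12; adjusted p = 0.453 with an estimated correlation), and Cyp51 was at -1.06 ± 0.234. Nucleoside genes were lower in 4 of 22 cases, Tk1, Dck, Dut (-1.18 ± 0.259) and Nme1 (-0.92 ± 0.21, uncertain with 12.5% of its exonic length shared), with a median of -0.21 (adjusted p = 0.0349; adjusted p = 0.453 with an estimated correlation). In the ErbB list 2 of 14 were higher, 4 adjusted over the list alone, with a median of 0.24 (adjusted p = 0.0155; adjusted p = 0.453 with an estimated correlation).

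Further lists lower in the combination-adapted organoids were S phase (-0.91, adjusted p = 2.97e-08, 6 genes adjusted over the list alone), G2 and mitosis (-1.79, 9.36e-12, 20 adjusted over the list alone), repair (-0.86, 6.23e-05, 5 adjusted over the list alone), oxidative phosphorylation (-0.24, 2.75e-05, 8 adjusted over the list alone) and fatty acid synthesis (-0.28, 0.00028, 5 adjusted over the list alone). Higher were MAPK output (0.26, adjusted p = 0.0177), YAP targets (0.51, 0.00196) and TGF-beta targets (0.55, 0.00186). The adjusted p with an estimated correlation was 0.453 to 0.611 over these 8 lists. Called members were Xrcc1 (-0.63 ± 0.128) and Fanca (-2.11 ± 0.525, uncertain) for repair, Cox6a1 (-0.89 ± 0.157) and Ndufa1 (-0.93 ± 0.211) for oxidative phosphorylation and Mlxipl (-0.99 ± 0.203) and Fads2 (-0.91 ± 0.223) for fatty acids. Outside these lists Slc4a4 was higher by 1.08 ± 0.197, Bcl2l11 by 0.72 ± 0.158, Wipi1 by 0.51 ± 0.117 and Maml2 by 0.55 ± 0.137, and Eno1 (-1.02 ± 0.174) and the endoplasmic reticulum stress genes Sdf2l1 (-0.83 ± 0.158) and Manf (-0.68 ± 0.156) were lower. Rrm2 (-1.59 ± 0.439, adjusted p = 0.0578), Mki67 (-1.91 ± 0.772, 0.172), Egfr (0.04 ± 0.313, 0.962) and Kras (0.30 ± 0.18, 0.368) did not pass the test.

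Whether the combination differed from the sum of the single drugs was tested with an interaction term. For adaptation edgeR called 0 genes, with 554 at an unadjusted p under 0.05 and 7 called by DESeq2, and for acute treatment it called 0, with 536 and 7. With the culture set term 39 genes were called for acute treatment, against 3 in the same 12 libraries without it. Spry4 in the acute design was at -0.58 ± 0.439 and Rrm2 at 0.47 ± 0.609, each with an adjusted p of 1. For adaptation camera called xenobiotic metabolism (-1.26, adjusted p = 0.000915) and ribosomal proteins (-0.22, 0.04) lower, and G2 and mitosis (1.19, 0.000915), NF-kB (0.72, 0.000295), hypoxia (0.30, 0.000228), cholesterol synthesis (0.33, 0.000228), fatty acid synthesis (0.29, 0.0113) and ductal epithelium (0.30, 0.00696) higher than the sum. The adjusted p with an estimated correlation was 0.183 for the xenobiotic and ductal lists and 0.87 to 0.91 for the others.

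For acute treatment camera called S phase (0.62, adjusted p = 0.00023), repair (0.38, 0.00363), oxidative phosphorylation (0.17, 0.00495), cholesterol synthesis (0.25, 0.00896) and ribosomal proteins (0.19, 0.00284) higher than the sum of the single drugs. Lower than the sum were MAPK output (-0.21, adjusted p = 0.0473), ErbB (-0.44, 0.00284), xenobiotic metabolism (-0.39, 0.0358), NF-kB (-0.70, 0.00122), hypoxia (-0.29, 0.00284), pH regulation (-0.19, 0.0211), the integrated stress response (-0.32, 0.00495), TGF-beta targets (-0.34, 0.0211), basal epithelium (-0.73, 0.00122) and mitochondrially encoded genes (-0.50, 0.00495). With an estimated correlation, the adjusted p was 0.363 for the ErbB and pH lists and 0.679 for the other 13.

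Adapted and acute changes of a drug share the same 3 controls, so their fold changes correlate without any effect. For erlotinib the correlation across 15888 genes was 0.27 (rank correlation 0.183), against 0.498 in 20 simulations of unchanged groups, and the covariance was 0.0889 against 0.155, a difference of -0.0663. For gemcitabine it was 0.515 (rank correlation 0.461) against 0.492, with a covariance of 0.201 against 0.153, a difference of 0.0472. For the combination it was 0.426 (rank correlation 0.372) against 0.491, with a covariance of 0.197 against 0.151, a difference of 0.0461. Genes with the same sign made up 56.3%, 67.2% and 61.6%, against 66.6%, 66.6% and 66.7% in the simulations. No gene was called in both by edgeR for any drug, and independent lists of these sizes would also share 0. The 3 controls are too few to give each comparison 2 of its own and were not split, so part of any excess may come from the shared controls, and genes are not independent replicates. The simulated groups have no culture sets, unlike the real ones, so the simulated values are not a fair expectation. The differences from them support no conclusion. Changes of different drug arms also share the same 3 controls, so genes and lists that recur across arms are not separate evidence.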

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

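The 3 tests on the cell cycle genes of acute treatment, the test of random gene sets and the test of library size were chosen after their results were seen. A further test on the cell cycle genes, of p53 activation, had been run and left undecided because p53 targets went in both directions, and the test of the 2 experiments then took its place. Adapted and acutely treated organoids differed by the test of the difference itself in 12 genes for erlotinib and in 438 genes for the combination. With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The highest number in the other splits was 0 in both cases. The same holds for acute erlotinib (real 2), acute gemcitabine (real 13) and the acute combination (real 550), where 1 split of 10, the real one, gave as many and the highest other was 0. The limit of 10 splits also holds for adaptation to erlotinib, where 3 of 10 splits gave the real number of 1. For adaptation to gemcitabine, adaptation to both drugs and adapted against acute gemcitabine the real number was 0. All 10 splits reach 0 by definition, so they say nothing about chance there, and the highest other was 0.

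For both interactions the real number was 0, which all 100 drawn splits reach by definition, so the splits say nothing about chance. The highest other was 10 for adaptation and 1075 for acute treatment, which points to a structure of the 12 control and acute libraries, but which structure it is was not tested. For week 12 against week 1, 1 of 100 splits, the real one, gave as many as 9610 genes and the highest other was 515, so chance can be excluded only if the 15 libraries are exchangeable; the week-1 libraries form 3 clusters, and 3 clusters against 3 libraries give too few splits.

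The first pattern is the lower expression of chromosome 4 in 6 adapted libraries, 2 from each arm. A few strongly changed genes are argued against, as the share of chromosome 4 genes below the control mean exceeded that of other autosomes by 25.4 to 45 percentage points, though the 6 libraries were picked for a low median, which makes some excess expected. Genes matched on expression and length had medians no farther from 0 than -0.02, which argues against a level or length effect. Over all 9 adapted libraries 0 of 100 random gene sets had a mean as low as chromosome 4 (-0.23, lowest random mean -0.02). Random sets lie near 0 because values are relative to the median of the autosomes, and chromosome 4 was picked after the data were seen. This test therefore cannot decide on chance. In each of the 6 libraries 8 of 8 windows along the chromosome lay below -0.1, as a chromosome 4 copy present in fewer cells would give, and this hypothesis stays open, since no DNA was measured here and the pattern was found in the same data. The 3 controls kept for the same time lay between -0.01 and 0.01. All values are relative to the mean of these controls, so a fall shared by all 3 would not show. With 3 controls, a part of the drugs in the pattern was not tested and stays open.

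The second pattern is the higher level of cell cycle genes after acute gemcitabine, alone or with erlotinib. The lowest of 18 within-set medians of the S phase, mitosis and repair lists was 0.56. This test cannot decide whether differences between culture sets play a part. The sets were found by matching deviations from group means, which draws each within-set difference toward that of the groups. Acute erlotinib came from the same experiment as the gemcitabine treatments, and the highest of its 3 list means was 0.04 ± 0.58 (SD over 3 sets). This argues against a difference between the 2 experiments only if erlotinib does not itself lower these genes. That was not tested apart from the experiment. Cells held in S phase alone would leave mitosis genes behind, yet these exceeded the S phase list by 0.95 ± 0.71 after gemcitabine and 1.04 ± 0.89 after the combination (SD over 3 sets), which is weak evidence because set 2 differed by only 0.17 and 0.02. A drug response in which more cells are in cycle, or in which cells collect between S phase and mitosis, may explain the pattern, and no value here separates these.

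The third pattern is the lower level of cell cycle genes in week-12 than in week-1 controls. Library size is argued against, with a ratio of mean totals of 1.02. A length bias of degraded RNA is argued against too: other genes matched on length and expression had a median log2 change of -0.22 (quartiles -0.58 to 0.35), against -2.84 for 48 cell cycle genes. Replication-dependent histone genes, which are in no list, had a median of -2.01, with 29 of 39 lower and 2 higher, as fewer dividing cells at week 12 may give. Whether this comes from 12 weeks in culture, from the time since the last passage or from the batch of each week was not tested, because week and batch cannot be told apart.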

How the results depend on the processing

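The surrogate variable fit, the fits of 12 libraries, the fits with a culture set term and the sums per cluster were chosen after the data were seen, and the cause was not tested where a number changed, unless stated. RLE scaling kept every count of genes within 1.5 times and moved the median of all genes by at most 0.02, and 382 of 382 values of named genes kept their side of the threshold. The labels give no replicate numbers that groups share, so no pairing came from them, and the fits with a culture set term below use sets found from the values instead. The culture sets found from the values follow the accession order in all 12 control and acute libraries, as a hint from the data and not the design.

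With no filter on low counts the calls were 3 for adapted erlotinib (1 in the report), 1 for adapted gemcitabine (0), 1 for acute erlotinib (2), 2 for acute gemcitabine (13), 286 for the acute combination (550; 284 shared), and 7, 1 and 213 for adapted against acute erlotinib, gemcitabine and both (12, 0 and 438). DESeq2 called 72, 31 and 74 in the adapted arms (erlotinib, gemcitabine, both), 35, 208 and 1431 in the acute arms, 298, 58 and 1355 for adapted against acute, and 7 for each interaction. On log2(TPM + 1) the calls were 3 for adapted gemcitabine, 1 for acute erlotinib (neither of the 2 in the report), and 27 and 7 for adapted against acute erlotinib and gemcitabine. The acute combination had 268 higher and 357 lower (287 and 263 in the report), and adapted against acute for both had 415 and 151 (183 and 255). Fitting only the groups of the contrast gave 0 for adapted erlotinib, the 3 acute arms and adapted against acute erlotinib, and 3 for the acute interaction; fewer libraries then estimate the spread. All 33 libraries in a fit gave 8 for adapted erlotinib, without Gpr55, which lost its call, and 8 for adapted both, 6, 179 and 1552 for the acute arms, and 190, 38 and 1485 for adapted against acute. Surrogate variables gave 111, 90 and 277 in the adapted arms, 4, 462 and 2162 in the acute arms (erlotinib, gemcitabine, both), 289, 208 and 2795 for adapted against acute, and 2 and 1 for the interactions. The 12 control and acute libraries alone gave 5, 7, 361 and 3 for the acute arms and interaction, and with a culture set term 142, 1296, 3566 and 39. With each adapted library in the set it correlates with best, a set term in the fit of all 21 libraries gave 25, 13 and 35 in the adapted arms (erlotinib, gemcitabine, both), 4, 370 and 1818 in the acute arms, 191, 4 and 1929 for adapted against acute, and 1 for each interaction. All counts with a culture set term, in acute and adapted arms, can be too high, since the sets were chosen by the same values.

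Of 122 camera calls, 0 held with an estimated correlation. With fry 37 lists were called, 17 of them not among the 122, and 102 of the 122 were lost. Of the fry calls, 29 were for week 12 against week 1. The acute combination against controls had 4, and adapted against acute organoids of the combination had 4. Fry called 0 lists in each other comparison, which include all adapted arms against controls, both single acute drugs and both interactions. Leaving out each library gave 0–13 calls for adapted erlotinib: 0 without each of control replicates 1, 2 and 3 and adapted replicates 1 and 2, and 13 without replicate 3. Ranges were 0–0 for adapted gemcitabine and 0–2 for adapted both (2 without adapted replicate 3). They were 0–2 for acute erlotinib (0 without controls 1, 2 or 3 or treated 1 or 3), 0–13 for acute gemcitabine (0 without controls 1 or 3 or treated 1 or 3, 4 without treated 2) and 16–814 for the acute combination (38 and 70 without controls 1 and 3, 130 and 16 without treated 1 and 2). For adapted against acute erlotinib the range was 0–52 (0 without adapted 1 or 2 or any acute library, 52 without adapted 3), for gemcitabine 0–2 (2 without adapted 3) and for both 10–395 (31, 31 and 88 without adapted 1, 2 and 3, 118 and 10 without acute 1 and 2). The adapted interaction gave 0–1 (1 without replicate 3 of erlotinib or of both), the acute interaction 0–0, week 12 against week 1 8519–9593 and list calls 104–138.

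With a library left out, list medians ranged as follows, and the direction turned where a library is named. G2 and mitosis went from -1.63 to 0.211 after adaptation to erlotinib (0.211 without control 2), from -0.393 to 1.2 after gemcitabine and from -0.269 to 1.3 after both (-0.393 and -0.269 without control 3). Ribosomal proteins went from -0.0403 to 0.276 for erlotinib (-0.0403 without adapted 1), from -0.358 to 0.0731 for gemcitabine (0.0731 without adapted 2) and from -0.395 to 0.0228 for the adapted interaction, where the test's direction turned without erlotinib 1 (-0.0147) or gemcitabine 1 (0.0228). Interferon-stimulated genes went from -0.375 (without adapted gemcitabine 2) to 2.52. Kras at week 12 against week 1 was -0.102 on log2(TPM + 1). Of 3935 values of named genes with a library left out, 439 lost their call and 7 gained one. Totals of 38000470 to 39875124 counts are close, so depth limits genes near the low-count filter alike in all groups, and with 3 libraries per group the simulated recovery was 14.9% at 1.5-fold.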

Other observations

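The culture sets, the values within them and the genes named in these paragraphs were chosen after the data were seen. Lgr5, a receptor of intestinal stem cells, was lower in each treated library than in the control of its set: the log2 differences were -1.11, -0.77 and -0.52 after acute erlotinib, -1.1, -0.76 and -0.81 after gemcitabine and -1.64, -1.88 and -1.01 after the combination. Reg3g, an antimicrobial lectin gene, was higher after acute erlotinib in each set, by 3.8, 1.73 and 3.18, but it changed by 0.75, -0.96 and -0.58 after gemcitabine and by 1.02, -1.49 and -1.03 after the combination. Spry4 changed by -0.35, -0.29 and -0.34 after erlotinib, by -0.43, -0.38 and -0.25 after gemcitabine and by -1.34, -1.66 and -1 after the combination. Replication-dependent histone genes, 24 of them tested at week 12, had a median log2 change of 1.57 after the acute combination, 0.99 after gemcitabine, 0.12 after erlotinib and -0.36, 0.31 and 0.44 after adaptation to erlotinib, gemcitabine and both. With a culture set term in the fit of 12 libraries, 25 of 27 S phase genes, 21 of 21 mitosis genes and 20 of 27 repair genes were called higher after the combination, and 17 of 20 NF-kB genes and 9 of 22 MAPK genes lower.

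When the treated and control library of 1 set were exchanged, the fit with a set term called 0 genes at most in 3 such exchanges for each acute arm, against 142, 1296 and 3566 without an exchange. An exchange moves a treatment difference into the spread between sets, so a low count was largely fixed in advance. The sets were not found anew in each exchange, and with 3 exchanges per arm no conclusion is drawn. Y-linked genes also differed between sets. Their geometric mean was 29.7 to 31.9 CPM in set 1, 22 to 31.8 in set 2 and 9.2 to 13.1 in set 3, and 25.9 to 40.5 in the adapted libraries. Week-1 clusters held 14.7 to 15.6, 22.7 to 24.6 and 9.29 to 11.7 CPM. Adapted libraries matched a set less closely, with correlations of 0.08 to 0.37. Of these, 8 of 9 matched best the set with their own number in accession order, and gemcitabine replicate 2 did not. Y-linked genes go against the match to set 3, which held 9.2 to 13.1 CPM. Replicate 3 of adapted erlotinib, gemcitabine and both had 30.7, 40.5 and 32.6 CPM.

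Other chromosomes stood apart in single adapted libraries, and chromosome 19 in whole week-1 clusters. Chromosome 10 was at 0.24 in adapted erlotinib replicate 1, and chromosomes 12 and 14 were at 0.23 and -0.38 in replicate 2. Relative to the mean of the week-1 controls, chromosome 19 lay at 0.24 to 0.27 in every library of week-1 cluster 2. It lay at -0.26 to -0.2 in every library of cluster 3. A chromosome-wide shift was thus also present between control clusters without drug.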
